A study of Mus musculus with 16 samples.

How the data were processed

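H3K27me3 was measured by ChIP-seq in female mouse embryonic stem cells of a C57BL6 and CAST hybrid, wild type (WT) or without SIRT7 (KO), at day 0 in LIF and at day 7 after LIF withdrawal. The 16 samples were 8 ChIP libraries, 2 in each of 4 groups, and 8 input libraries that were not analysed here. Per the labels, synthetic nucleosome spike-ins were added to the chromatin, and whether they entered the peak calls is not stated.

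The authors' processing notes name FastQC 0.11.3, Trimmomatic 0.36, Bowtie2 2.2.9, SAMtools 0.1.19, deepTools 2.4.2 and MACS2 2.2.7.1, and the mouse build mm10, without giving the role of each. The 48 deposited peak lists comprised 4 per library (32 lists) and 16 called on the pooled libraries of a group. The 4 kinds of list came from all reads, from reads assigned to genome1, from reads assigned to genome2 and from reads assigned to neither, and which parent genome1 or genome2 is, is not stated. In the deposited lists the authors gave each peak a fold enrichment over background, a ratio, and its significance as -log10 q (neg_log10_p). The lowest -log10 q was between 1.00 and 1.10 in every list, so the lists end at a q of 0.1. Read counts are not part of these lists, so the read depth behind each list is unknown, and the number of peaks and the covered length describe how much was called. Fold enrichments were not tested between libraries, and the medians and single values given are descriptions only.

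The covered length was the number of bases under at least 1 peak, in Mb, for chromosome X and for the 19 autosomes. The X to autosome ratio was the log2 of their quotient per library. The allelic X ratio was the log2 of that quotient in the genome1 list over that in the genome2 list, so that the autosomes of each list served as its own standard. Group means were compared by two-sided exact permutation tests. Standard errors treat the libraries as unpaired, and those given as within replicate numbers come from the 2 differences between libraries of the same number. An error from only 2 differences can be small by accident and does not show precision. With 2 libraries against 2 there are 6 arrangements and the smallest p is 0.333. Tests over both days or both genotypes permuted within strata, over 36 arrangements, with a smallest p of 0.0556.

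For tests across the genome, the covered fraction (0 to 1) of a window by the all-read peaks of a library was fitted with limma 3.58.1 (lmFit and eBayes with trend and robust, 4 group means, contrasts for genotype at each day, day in each genotype and their interaction), with Benjamini-Hochberg adjustment over all windows tested and a threshold of 0.05. Windows of 100 kb with a mean covered fraction above 0.01 were tested. Gene windows came from a table of 34328 genes (21631 protein coding, 12697 lncRNA, 1255 of all on X). That table gives no strand, so the gene window was the 2.5 kb on each side of the gene's start or end coordinate, whichever had the larger mean coverage over all 8 libraries, without regard to group. A gene window is therefore not always the promoter, and taking the more covered end raises the levels. A gene with a bare promoter and a covered far end counts as covered. The choice of end departs from the design, which asked for the transcription start site. Gene windows with a mean above 0.05 were tested, and windows with 1 value in all 8 libraries, such as Hox genes covered in full throughout, carry no spread and were not tested.

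Of 410 genes in 20 lists, 405 matched the table by symbol and 5 did not. The lists, the named-gene rule, the tests and most alternatives were fixed before the data were examined. Lists with 5 or more tested members were tested with camera (limma), with a preset correlation of 0.01 and again with an estimated correlation, to which the same at equal area was added later. List means cover the tested members unless stated. Camera compares a list with all other windows, so a list can pass as higher where its own mean did not move and the other windows were lower. Named genes were, per contrast, the 8 with the largest difference in each direction among those past the threshold with both libraries of a group above both of the other, filled where fewer passed with the largest gaps between groups, which are said not to have passed. To these were added up to 4 members of each list with the largest difference, and Sirt7 and Xist. Ties were broken by the mean of the higher group and then by symbol, so genes listed at a difference of 1 stand first by the alphabet. Gene models without a name of their own were not named. Windows followed the same rule with 5 per contrast, and no rule applied to the interaction.

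The tests were run on simulated data with the spread of these libraries. With 200 of 16444 gene windows changed, the gene test recovered 0% of changes of 0.3 and 0% of changes of 0.9. With 1600 changed, it recovered at most 1.88% of the smaller and 40.9% of the larger. The 100 kb test recovered 29.0 to 33.0% of changes of 0.3 and 94.0 to 96.0% of changes of 0.9 with 200 changed. With 1600 changed it recovered 67.4 to 71.0% and 97.4 to 98.5%. The median spread within groups (SD of the covered fraction) was 0.197 for gene windows and 0.0506 for 100 kb windows. The case with 200 changed and no limit to the 0 to 1 range was set first, and the others were added after its result was seen. A count of 0 genes between genotypes thus says little of few or small changes, and the 100 kb windows are the more informative test.

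Peak names in the 16 lists of replicate number 1 share a prefix that differs from the prefix shared by the 16 lists of number 2. Deviations from the group mean correlated between groups in every pair, from 0.108 to 0.456 for gene windows and from 0.349 to 0.696 for 100 kb windows, so the replicate number was treated as a batch. Each batch holds 1 library of each group. Values within replicate numbers are given beside group differences, and a fit with the replicate block gave 941 gene windows for day 7 against day 0 in WT and 1008 in KO. The main fit has no such term, so its spread includes the difference between replicate numbers. Between genotypes the block gave 0 genes and 0 windows of 100 kb at either day.

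Alternatives were a stricter peak threshold (-log10 q of 2), lists cut to equal autosomal length by their best peaks (equal area), the replicate block, leaving out each library, other windows (1 kb and 5 kb on each side, 1 Mb), no filter, centred fractions, plain eBayes, numbers of peaks, the unassigned, summed and pooled lists, and a rule that counts a peak as shared when at least 50% of it is covered. For the allelic ratio, equal area cut the lists of each genome to the shortest list of that genome. Gene bodies with 2.5 kb on each side, equal area among the day 7 libraries, the genome1 and genome2 lists of a library cut to equal autosomal length, and equal area without WT day 0 replicate 1 were chosen after seeing the data. Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9, and R 4.3.3, were used.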

Results

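H3K27me3, the repressive mark laid down by the Polycomb PRC2 complex, was mapped in WT and SIRT7-KO female embryonic stem cells before and after LIF withdrawal, when such cells leave pluripotency and silence an X chromosome. SIRT7 is a sirtuin deacylase of the nucleus. The series title concerns dosage compensation and the female X, so chromosome X was compared with the autosomes. The all-read lists held 62107 and 70502 peaks in the WT day 0 libraries, 88958 and 54236 in KO day 0, 53305 and 42371 in WT day 7, and 38038 and 25610 in KO day 7. Median peak lengths were 637 to 902 bp in the 4 libraries numbered 1 and 1727 to 2101 bp in the 4 numbered 2. The share of the union of covered bases that both replicates covered was 0.220 in WT day 0, 0.344 in KO day 0, 0.497 in WT day 7 and 0.613 in KO day 7. Between WT and KO libraries of the same number (1 and 2) it was 0.377 and 0.462 at day 0. At day 7 it was 0.659 and 0.566. These lay above the replicates of a group, except that the KO day 7 replicates lay between the day 7 values.

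In WT cells, chromosome X went from sparse coverage at day 0 to broad coverage at day 7. Of 1279 tested X windows of 100 kb, 685 rose, 8 of the 12249 autosomal windows rose as well, and 1 autosomal window fell. The windows with the largest differences included those over Gpc3, a heparan sulphate proteoglycan gene (X, 52400001 to 52500000), Usp9x and Ubl4a with its neighbours (X, 74300001 to 74400000). Over Gpc3 the covered fraction was 0 in both day 0 libraries and 1.00 in both day 7 libraries (adjusted p = 0.000473). X peaks covered 8.88 Mb ± 9.71 (SD, n = 2) at day 0 and 69.7 Mb ± 3.79 at day 7, against 161.5 Mb ± 134.8 and 106.9 Mb ± 52.2 on the autosomes. The median fold enrichment of the peaks was 2.71 ± 0.899 at day 0 and 2.33 ± 0.726 at day 7. The log2 X to autosome ratio was 4.00 ± 0.68 (SE) higher at day 7 (± 0.97 within replicate numbers), by 4.97 within replicate number 1 and 3.04 within number 2 (exact permutation p = 0.333, the smallest 2 against 2 allows).

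At gene windows in WT, 575 rose, 431 of them on X, and 6 fell, all autosomal (limma). Among those first by the naming rule, Aifm1, Alas2, the erythroid enzyme of haem synthesis, Akap17b and Alg13 lie on X. They went from 0 in both day 0 libraries to 1.00 in both day 7 libraries (adjusted p = 0.0185 each). The autosomal Abr and Adap1 did the same (adjusted p = 0.0205 and 0.0187). Ier5, an immediate early gene on chromosome 1 (155096367 to 155099636), fell from 0.851 ± 0.211 (SD, n = 2) to 0 (adjusted p = 0.0470), and Svs1 fell from 0.567 ± 0.119 to 0.0157 ± 0.0222 (adjusted p = 0.0492). Slc45a2, Grina, Nctc1, Nod2, Tmem176a and Rarres2 were lower at day 7 by 0.704 to 0.962 and did not pass. With the replicate block Slc45a2, Grina, Nctc1 and Rarres2 passed (adjusted p = 0.0475, 0.0192, 0.0190 and 0.0332), and with centred fractions Tmem176a passed (0.0483). The window of Xist, the RNA that coats the inactive X, was 0.235 ± 0.0457 at day 0 and 0.249 ± 0.352 at day 7 (adjusted p = 0.992). The replicate block gave 910 up and 31 down, and lists of equal area 1040 up and 146 down, with 230 up and 31 down among 100 kb windows. At equal area 319 of the 1040 genes and 160 of the 230 windows lay on X, so that 721 of the genes that rose were autosomal. At equal area Akap17b and Alas2 differed by 0.50 and no longer passed, nor did Ier5 (-0.351), and Ier5 and Svs1 did not pass with -log10 q of 2 or more (-0.851 and -0.310). With 5 kb on each side Ier5 and Svs1 did not pass either, nor Adap1 over its gene body (0.140). Leaving out any of the 4 day 7 libraries gave 0 genes. Without KO day 0 replicate 1 there were 312, without WT day 0 replicate 2 there were 1076, and without WT day 0 replicate 1 there were 3091 genes and 6689 windows of 100 kb. Most of the last were falls, at 2174 of the genes and 5834 of the windows, 5812 of them autosomal.

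In KO cells the same comparison gave 964 X windows of 100 kb that rose, with 4 autosomal ones, while 9 autosomal windows fell. Windows over Gpc3 and Huwe1, a ubiquitin ligase gene, went from 0 to 1.00 in both libraries (adjusted p = 0.000248). X peaks covered 8.26 Mb ± 6.48 (SD, n = 2) at day 0 and 85.0 Mb ± 3.28 at day 7, and autosomal peaks 123.8 Mb ± 44.6 and 61.7 Mb ± 16.6, with median fold enrichments of 2.43 ± 0.740 and 2.31 ± 0.614. The log2 ratio was 4.61 ± 0.61 (SE) higher at day 7 (± 0.84 within replicate numbers), by 5.45 and 3.77 within replicate numbers 1 and 2 (exact permutation p = 0.333, again the smallest possible). Over both genotypes the day difference was 4.31 (exact stratified permutation p = 0.0556, the smallest possible). Of the autosomal windows, 7414 (60.5%) were lower in both KO day 7 libraries than in both KO day 0 libraries, and 2086 (17.03%) in WT. Chance gives 16.7% for windows that vary on their own, but the windows of a library share the length of its list, so these shares test nothing.

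Gene windows in KO rose at 583 genes, 475 of them on X, and fell at 6. Aifm1, Akap17b and Alas2 again went from 0 to 1.00 in both libraries, as did Acot9 and Adgrg4 (adjusted p = 0.0177 to 0.0250). Ier5 fell from 0.992 ± 0.0115 (SD, n = 2) to 0 (adjusted p = 0.0251), Nctc1 from 0.915 ± 0.120 to 0 (adjusted p = 0.0428) and C1qtnf7 from 0.500 ± 0.00113 to 0 (adjusted p = 0.0325). Krt18, a keratin gene of simple epithelia, was at 1.00 in both day 0 libraries and 0 in both day 7 libraries without passing (adjusted p = 0.104), and Cyp21a1, Etnppl, Bspry and Arhgap33os were lower by 0.894 to 0.996 without passing. With the replicate block Krt18 and Arhgap33os passed (adjusted p = 0.0302 and 0.0405), and at equal area Krt18 and Bspry (0.0326 and 0.00919). Xist was 0.334 ± 0.354 at day 0 and 0.168 ± 0.121 at day 7 (adjusted p = 0.781). Of the genes that rose, 506 rose in both genotypes, where 20.4 would be shared if the calls were independent, and 2 fell in both. The 20.4 spreads the calls over all chromosomes, although 431 in WT and 475 in KO lie on X. Both comparisons also share 1 estimate of spread per window. The excess over 20.4 thus does not measure agreement at single genes. The replicate block gave 891 up and 117 down, with 1061 up and 89 down among 100 kb windows. Lists of equal area gave 943 genes up, 337 of them on X, and 113 down, and 401 windows up, 327 of them on X, and 33 down. At equal area Akap17b, Alas2, Acot9 and Adgrg4 still differed by 1 but did not pass (adjusted p = 0.111 each). There Ier5 was at 0 at both days, Nctc1 differed by -0.415 without passing, and with -log10 q of 2 or more Ier5, Nctc1 and C1qtnf7 did not pass (-0.50, -0.915 and -0.250), nor with 5 kb on each side. Leaving out any of the 4 KO libraries gave 0 genes, and without WT day 0 replicate 1 or replicate 2 there were 1396 (377 of them down) or 1210 (278 down), with 1719 windows of 100 kb without the former (642 down).

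**Figure D1:**
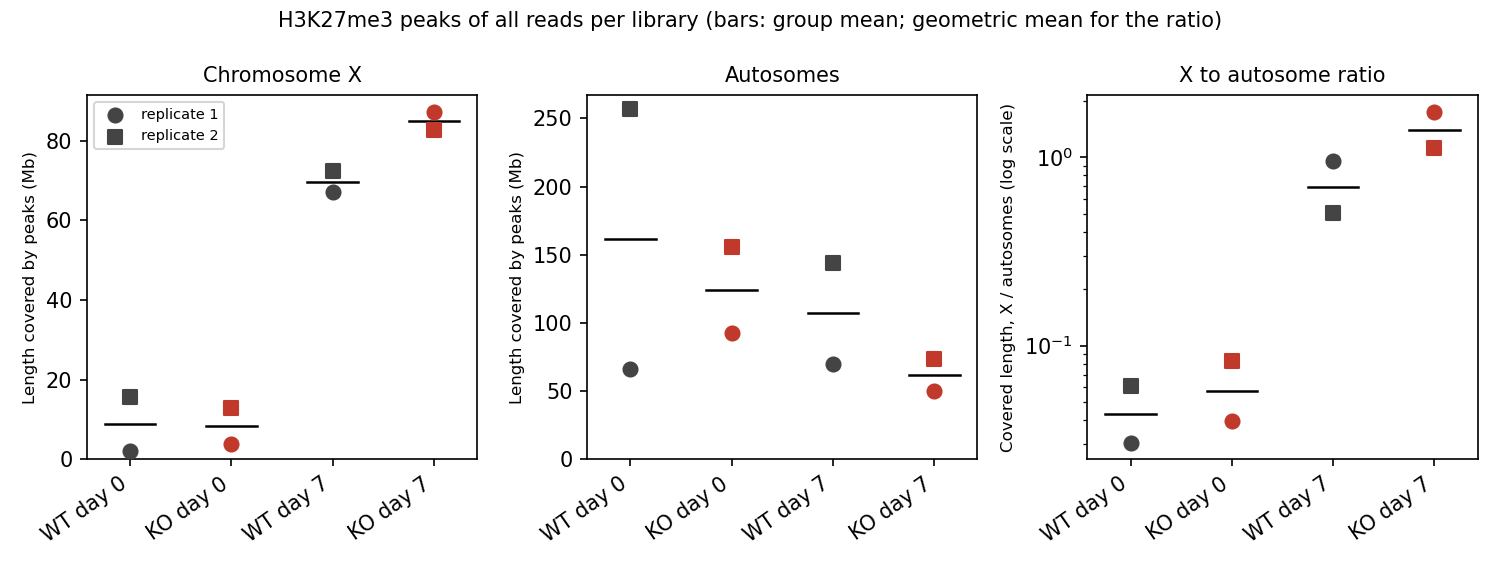
Length covered by peaks of all reads (Mb) on chromosome X and on the autosomes, and their ratio on a log axis, per library, with circles for replicate 1, squares for replicate 2 and bars for the group mean (geometric for the ratio). X coverage was 67.1 and 72.4 Mb in the WT day 7 libraries and 87.3 and 82.6 Mb in the KO day 7 libraries.

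X-linked genes subject to inactivation moved together between the days. In WT, 28 of 30 rose (29 adjusted over the list alone) and in KO 26 of 30 (29). Among them were Atrx, a chromatin remodeller gene, Atp7a, a copper transporter gene, Cul4b and Dkc1. The list means went from 0.0161 to 0.980 in WT and from 0.0162 to 0.982 in KO. At equal area 13 of 30 rose in each genotype, and Atp7a, Cul4b and Dkc1 no longer passed (0.50 with adjusted p = 0.484 in WT, 1.00 with 0.111 in KO). For comparison, of all 1093 X gene windows tested, 431 rose in WT and 475 in KO. Of 16 tested genes that escape X inactivation, 8 rose in WT (12 over the list alone) and 9 in KO (13), including Kdm5c, a histone demethylase gene, Med14 and Pbdc1 in both. At equal area 7 rose in each, without Med14, and Kdm5c did not pass over its gene body. Around the X inactivation centre 3 of 13 rose in WT (6 over the list alone) and 5 in KO (6). Rlim and Tsx were among those in WT and Chic1 and Nexmif among those in KO, and with the replicate block Nexmif passed in WT as well (adjusted p = 0.0204). Of the Rhox homeobox genes Rhox5 alone passed in each genotype, of 12 tested (3 and 4 over the list alone), from 0 to 0.867 ± 0.0433 (SD, n = 2) in WT and to 1.00 in KO. At equal area Rhox5 did not pass (0.418 in WT and 0.50 in KO, adjusted p = 0.555 and 0.552), while 4 and 3 of 12 Rhox genes did. It did not pass over its gene body in either genotype, nor with 5 kb on each side in WT (adjusted p = 0.0760). As a list test, camera set these lists against all other windows, most of them autosomal. A list on X could therefore pass because X as a whole rose, and its p says nothing particular to the list. Camera gave the genes subject to inactivation adjusted p = 2.05e-36 in WT and 1.15e-40 in KO (0.00563 for both as adjusted p with an estimated correlation), and escape genes 4.85e-13 and 3.44e-16 (adjusted p = 0.0504 and 0.0391 with an estimated correlation). The inactivation centre (adjusted p = 0.000252 and 0.000191) and the Rhox genes (0.00113 and 0.000191) did not hold, with adjusted p = 0.999 with an estimated correlation. At equal area with an estimated correlation 0 lists passed in any contrast, the genes subject to inactivation included (adjusted p = 0.885 in WT and 0.872 in KO), a test added after the other results were seen.

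Naive and general pluripotency genes, which sustain the undifferentiated state, rose at 8 of 18 tested members in WT (15 adjusted over the list alone) and 9 in KO (13). Sox2, a core pluripotency factor gene, and Fgf4, a growth factor gene, went from 0 to 1.00 in both genotypes, and further members that rose included Lefty1 and Tfcp2l1 in WT and Prdm14 and Nr0b1 in KO. Means of the 18 went from 0.0721 to 0.734 in WT and from 0.0503 to 0.706 in KO, and of all 28 matched members, 10 of them covered too little to test, from 0.0480 to 0.472 and from 0.0333 to 0.454. The 18 passed as a list (camera adjusted p = 7.8e-13 and 3.01e-14, and adjusted p = 0.0355 for both with an estimated correlation), but not with that correlation at equal area (adjusted p = 0.152 for both). In KO Nr0b1 did not pass with 1 kb on each side, nor Prdm14 over its gene body. Of 14 tested formative and primed pluripotency genes, 3 rose in each genotype (3 over the list alone), Nodal and Foxd3 among them. With 5 kb on each side Nodal did not pass in either, nor Foxd3 in WT, and the list did not pass (adjusted p = 0.163 and 0.0634). Usp26 and Magea4, X-linked members of the 22 tested germline genes, rose in both, as did Tex13a, also on X (0.912 ± 0.124 against 0.062 ± 0.0877 in WT, SD, n = 2), and the list did not pass (adjusted p = 0.946 and 0.688). None of the 3 passed at equal area (0.50, 0.50 and 0.412 in WT, with adjusted p = 0.484 each, and 1.00 each in KO, with 0.111, 0.111 and 0.0843), nor Tex13a with 1 kb on each side. At equal area the list passed as lower at day 7 in KO (adjusted p = 0.00852), with 3 of 17 tested members down, Dazl, Stag3 and Tdrd1, named after this was seen. It did not pass at equal area with an estimated correlation (adjusted p = 0.885), nor on the lists as deposited with an estimated correlation (0.999) or the replicate block (0.362).

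Developmental regulators, the classical targets of Polycomb, were covered at both days. Hox genes, which set position along the body axis, had list means of 0.922 at day 0 and 0.998 at day 7 in WT, and 0.928 and 0.998 in KO, with 0 of 22 tested members passing (camera adjusted p = 0.308 and 0.159). Neuroectoderm regulators were at 0.837 and 0.989 in WT, with 0 of 27 passing, such as Otx2 at 0.608 ± 0.555 (SD, n = 2) and 1.00 (list adjusted p = 0.0214 in WT and 0.112 in KO, and in WT adjusted p = 0.999 with an estimated correlation and 0.691 at equal area). Mesoderm and endoderm regulators were at 0.781 and 0.867 in WT (adjusted p = 0.258). Markers of neurons and glia, a cell type that could arise after LIF withdrawal, were at 0.446 and 0.805 in WT and 0.474 and 0.788 in KO. Of these 12, 0 passed over all genes, and 3 in WT and 2 in KO adjusted over the list alone, with Tubb3, a neuronal tubulin gene, at 0.323 ± 0.0222 and 1.00 in WT. Tubb3 passed over all genes with the replicate block (adjusted p = 0.0165 in WT and 0.0144 in KO) and at equal area (0.00921 and 0.00887). The list passed in both, but not with an estimated correlation (list adjusted p = 0.00538 and 0.00588, and adjusted p = 0.999 with an estimated correlation).

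The other lists did not pass between the days in WT or KO. Camera adjusted p in WT was 0.935 for imprinted genes, 0.421 for non-canonically imprinted genes, 0.680 for Polycomb and H3K27 enzymes, 0.934 for fibroblast markers, which would report feeder cells, 0.926 for trophectoderm markers and 0.701 for primitive and visceral endoderm markers, with 0 members passing in each. Housekeeping and ribosomal protein genes, as controls that are expressed in all cells, had 4 of 20 and 2 of 25 members covered enough to test, and 0 passed. Of the 7 sirtuins 0 were covered enough to test, and the window of Sirt7 held no peak in any of the 8 all-read lists.

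**Figure D2:**
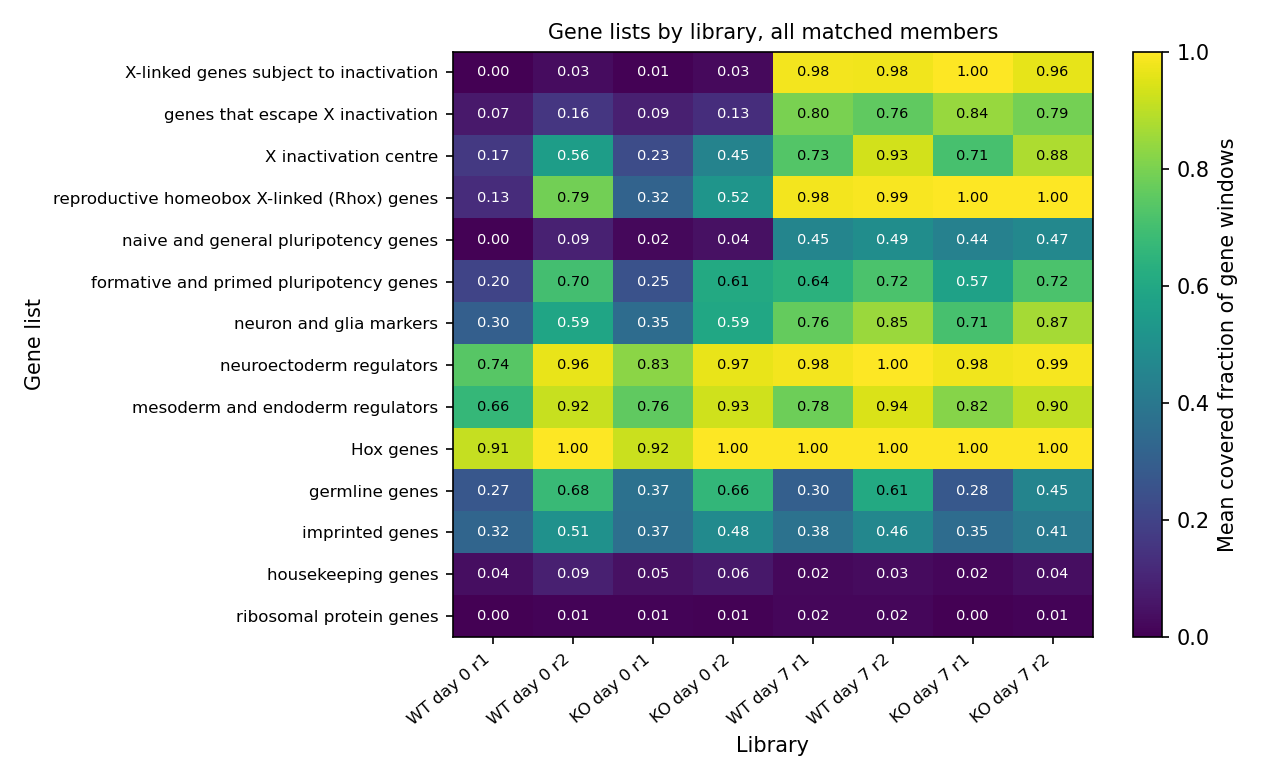
Mean covered fraction (0 to 1, by colour and number) of the gene windows of 14 fixed lists (vertical axis) in each of the 8 libraries (horizontal axis), over all matched members. X-linked genes subject to inactivation went from group means of 0.0161 and 0.0162 at day 0 to 0.980 and 0.982 at day 7.

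At day 7, the KO libraries had on average more of X and less of the autosomes under peaks than the WT libraries. Of the X windows of 100 kb, 691 of 1279 (54.0%) were higher in both KO libraries than in both WT libraries and 2 were lower. Of the autosomal windows 83 were higher and 3462 of 12249 (28.3%) lower, where chance gives 16.7% in each direction for windows that vary on their own, which those of a library do not. Of the gene windows on X, 83 of 1093 (7.59%) were higher in both KO libraries and 1 lower, and of the autosomal ones 174 higher and 2749 (17.9%) lower. The gene windows on X averaged 0.915 in KO and 0.871 in WT. A covered fraction cannot exceed 1, so many of them could hardly be higher in KO. Mean coverage was 0.663 in KO and 0.545 in WT over X windows of 100 kb and 0.0500 and 0.0865 over autosomal ones. X peaks covered 85.0 Mb ± 3.28 (SD, n = 2) in KO and 69.7 Mb ± 3.79 in WT, 1.30 and 1.14 times as much within replicate numbers 1 and 2, and autosomal peaks 0.713 and 0.511 times as much. Autosomal lengths overlapped between the genotypes, with WT replicate 1 at 70.0 Mb and KO replicate 2 at 73.5 Mb. Their log2 difference was -0.73 ± 0.59 (SE, exact permutation p = 0.667). The log2 X to autosome ratio was 1.01 ± 0.56 (SE) higher in KO (± 0.15 within replicate numbers), by 0.87 and 1.16 within numbers 1 and 2, with median fold enrichments of 2.31 ± 0.614 and 2.33 ± 0.726. The exact permutation p was 0.333, the smallest 2 against 2 allows, and over both days the genotype difference was 0.71 (exact stratified permutation p = 0.167, exact paired p = 0.125, the smallest 4 pairs allow).

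By name, 6 of the 8 genes with the largest gaps towards KO at day 7 lie on X. They were Dmd, the dystrophin gene (1.00 in KO against 0.625 ± 0.042 in WT, SD, n = 2), Chm (1.00 against 0.588 ± 0.144), Cldn34b2, Pof1b, Magea1 and Ott, and the autosomal ones were Zkscan2 and Ppp1r3c. Towards WT stood the neighbours Lrrc46 (0.0165 ± 0.0233 against 0.952 ± 0.0686) and Scrn2 on chromosome 11, Col6a3, a collagen gene, Lypd2, Dennd1c, Akap3, Spdef and Il17re, all autosomal. The 100 kb windows with the largest differences were lower in KO over Prdm16 on chromosome 4 (0.170 ± 0.0220 against 0.740 ± 0.121), Wnt7a and Atp2b2 on chromosome 6, and higher over Tex16 on X (0.556 ± 0.0441 against 0.169 ± 0.0479). None of these passed, and at equal area Lrrc46 and Scrn2 differed by 0.0165 the other way. In limma 0 of 16444 genes passed (287 at an unadjusted p under 0.05) and 0 of 13528 windows (363). With the replicate block 0 of each passed as well, with 702 genes and 774 windows at an unadjusted limma p under 0.05. In simulations of this contrast the gene test recovered 0% of 200 changes, and with 1600 changed 34.5 to 38.8% of changes of 0.9 and at most 1.88% of changes of 0.3. The 100 kb test recovered 95.0 to 96.0% of changes of 0.9 and 33.0% of changes of 0.3, with 200 changed. With 1600 changed these were 97.9 to 98.5% and 67.9 to 71.0%. Mean coverage over X windows of 100 kb, 0.663 in KO and 0.545 in WT, differed by less than either simulated change. Simulated windows varied on their own, which those of a library do not.

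Between genotypes at day 7, escape genes had a list mean of 0.868 in KO and 0.825 in WT. These are levels at the more covered end of each gene and do not give the coverage of escape gene promoters. Tmem29 stood at 1.00 against 0.604 ± 0.171 and Mid1 at 1.00 against 0.806 ± 0.274 (SD, n = 2). Genes subject to inactivation were at 0.982 and 0.980, with Ogt at 0.674 ± 0.461 against 0.535 ± 0.284. A covered fraction cannot exceed 1, so as a list these genes had almost no room to be higher in KO. Rhox genes were at 1.00 and 0.988, mesoderm and endoderm regulators at 0.868 and 0.867 and Hox genes at 0.998 and 0.998. These 5 lists passed camera as higher relative to the other genes, whose autosomal mean was 0.313 in KO and 0.413 in WT (adjusted p = 0.000584, 0.0121, 0.0359, 0.0123 and 0.0422). Their median differences were 0, and 0 members passed, also over the list alone. With an estimated correlation all were lost (adjusted p = 0.345, 0.326, 0.999, 0.999 and 0.999), and 0 lists passed without KO day 7 replicate 1 and 1 without WT day 7 replicate 2. On lists of equal area the 3 X-linked lists passed (adjusted p = 0.0141, 0.00216 and 0.0474) and the others did not, and with an estimated correlation as well none did (adjusted p = 0.999 each). With the replicate block neuroectoderm regulators, at 0.980 in KO and 0.989 in WT, passed as well (camera adjusted p = 0.0326). They did not pass in the main fit (0.0552), nor there with an estimated correlation (0.999). Naive pluripotency genes were at 0.706 and 0.734 (adjusted p = 0.168), with Esrrb at 0 in KO and 0.562 ± 0.619 in WT, and imprinted genes at 0.526 and 0.582 (adjusted p = 0.362), with Ndn at 0 and 0.395 ± 0.559.

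At day 0, X coverage differed less between KO and WT cells than between the replicates of either. X peaks covered 8.26 Mb ± 6.48 (SD, n = 2) in KO and 8.88 Mb ± 9.71 in WT. The genes with the largest gaps towards KO included C1qtnf7 (0.500 ± 0.00113 against 0), Olfr55, Kcnab1, Cemip2, Crispld1, Fthl17-ps1 and Cldn1. Towards WT they were Prxl2b (0.0602 ± 0.0851 against 0.694 ± 0.00438), Mcc, Svs1, Orai2, a calcium channel gene, Enpp7, Tmem88b, Mef2b and C4b. Windows of 100 kb on chromosome 7 between 95500001 and 96000000 were higher in KO, up to 0.472 ± 0.0132 against 0.145 ± 0.00324, and a window over Fbln2 on chromosome 6 was lower (0.195 ± 0.0107 against 0.521 ± 0.196). None passed. In limma 0 genes (197 at an unadjusted p under 0.05) and 0 windows (69) passed, and 0 of each with the replicate block (343 and 243). The log2 X to autosome ratio was 0.41 ± 0.73 (SE) higher in KO (± 0.022 within replicate numbers), by 0.39 and 0.43 within numbers 1 and 2 (exact permutation p = 0.667), and the sign turned without WT day 0 replicate 1 (-0.09) or KO day 0 replicate 2 (-0.12), which sets different replicate numbers against each other. Without WT day 0 replicate 1, 1397 genes and 2900 windows passed, 1379 and 2891 of them lower in KO.

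Of the lists tested at day 0, 3 passed camera as higher in KO than in WT, and none of the 3 held with an estimated correlation or at equal area. Mesoderm and endoderm regulators had means of 0.844 and 0.781, such as Eomes at 0.777 ± 0.315 against 0.577 ± 0.0762 (SD, n = 2). Neuroectoderm regulators had 0.885 and 0.837, such as Nkx6-1 at 1.00 against 0.760 ± 0.339, and trophectoderm markers 0.831 and 0.740, such as Krt18 at 1.00 against 0.710 ± 0.410. Camera gave adjusted p = 0.00186, 0.00263 and 0.0203, all with adjusted p = 0.999 with an estimated correlation and 0.253, 0.472 and 0.607 on lists of equal area, and 0 members passed, also over the list alone. The gaps lay mostly in replicate 1. Over all members, list means in KO and WT were 0.757 and 0.665 for mesoderm and endoderm, 0.827 and 0.742 for neuroectoderm and 0.644 and 0.515 for trophectoderm there, and 0.926 and 0.917, 0.967 and 0.965, and 0.886 and 0.859 in replicate 2. Hox genes were at 0.928 and 0.922 and did not pass (adjusted p = 0.386). Without WT day 0 replicate 1, 1 list passed. Genes subject to inactivation were at 0.0162 and 0.0161 and escape genes at 0.116 and 0.120.

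The change from day 0 to day 7 was then compared between the genotypes. For the log2 X to autosome ratio the change in KO exceeded that in WT by 0.61 ± 0.92 (SE), less than this error, which includes the difference between replicate numbers. Within numbers 1 and 2 it was 0.48 and 0.73 (± 0.12 within replicate numbers). The genotype differences of the 2 numbers at day 7 lay above those at day 0 (exact permutation p = 0.333, the smallest possible). In limma 0 genes (99 at an unadjusted p under 0.05) and 0 windows (94) passed the interaction, and 823 and 538 did without WT day 0 replicate 1, 814 and 538 of them with the higher change in KO. The lists nearest to the threshold were the escape genes (adjusted p = 0.0746) and the Rhox genes (0.236), and 0 lists passed with all libraries, against 5 without WT day 0 replicate 2, 2 without KO day 0 replicate 1, and 1 each without KO day 7 replicate 2, WT day 0 replicate 1 or WT day 7 replicate 1.

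At day 7 genome1 peaks covered more of X than genome2 peaks in both genotypes. Genome1 peaks covered 23.4 and 62.0 Mb of X in the WT libraries and 37.4 and 71.9 Mb in the KO libraries, and genome2 peaks 0.916 and 7.00 Mb in WT and 1.29 and 6.71 Mb in KO. Peaks of reads assigned to neither covered 56.2 and 55.0 Mb in WT and 76.6 and 57.4 Mb in KO, more than genome1 peaks in replicate 1. Genes subject to inactivation with at least 50% of the window covered numbered 13 and 24 of 30 by genome1 in WT, 18 and 26 in KO, and 0 and 1 by genome2 in each genotype. Escape genes numbered 8 and 12 of 17 by genome1 in WT, 8 and 11 in KO, and 0 and 3 or 0 and 1 by genome2. Of all X genes, 405 and 648 in WT and 550 and 708 in KO were covered by genome1 alone, and 3 to 14 per library by genome2 alone. Autosomal lists were longer for genome1 too, at 17.2 and 127.8 Mb against 12.2 and 63.1 Mb in WT, so the allelic X ratio sets X against the autosomes of each list. Its log2 value was 3.15 ± 1.45 (SD, n = 2) in WT and 3.48 ± 1.46 in KO, a difference of 0.33 ± 1.45 (SE) or ± 0.0085 within replicate numbers, 0.34 and 0.32 within numbers 1 and 2 (exact permutation p = 0.667). The sign of the difference turned without WT day 7 replicate 2 (-0.69) or KO day 7 replicate 1 (-0.70), which sets libraries of different replicate numbers against each other. The level itself depended on how the lists were cut. With the genome1 and genome2 lists of each library at equal autosomal length it was 3.99 and 2.95 in the WT libraries and 4.54 and 3.29 in the KO libraries. With every list cut to its best peaks, down to the shortest day 7 list of its genome, it was 3.90 and 4.51 in the replicate 1 libraries but -1.40 (WT) and -1.25 (KO) in replicate 2, where 2 and 7 X peaks of genome1 were left. By number of peaks it was 3.35 (WT) and 3.29 (KO) in the replicate 1 libraries, and 0.057 and 0.079 in the replicate 2 libraries. At day 0 the ratio exists for replicate 2 only, at -0.74 in WT and -0.87 in KO, since the genome1 lists of replicate 1 held 351 and 2372 peaks with 0 on X, so the day difference was 2.87 in WT and 3.32 in KO. It came from 1 library per group and was not tested.

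**Figure D3:**
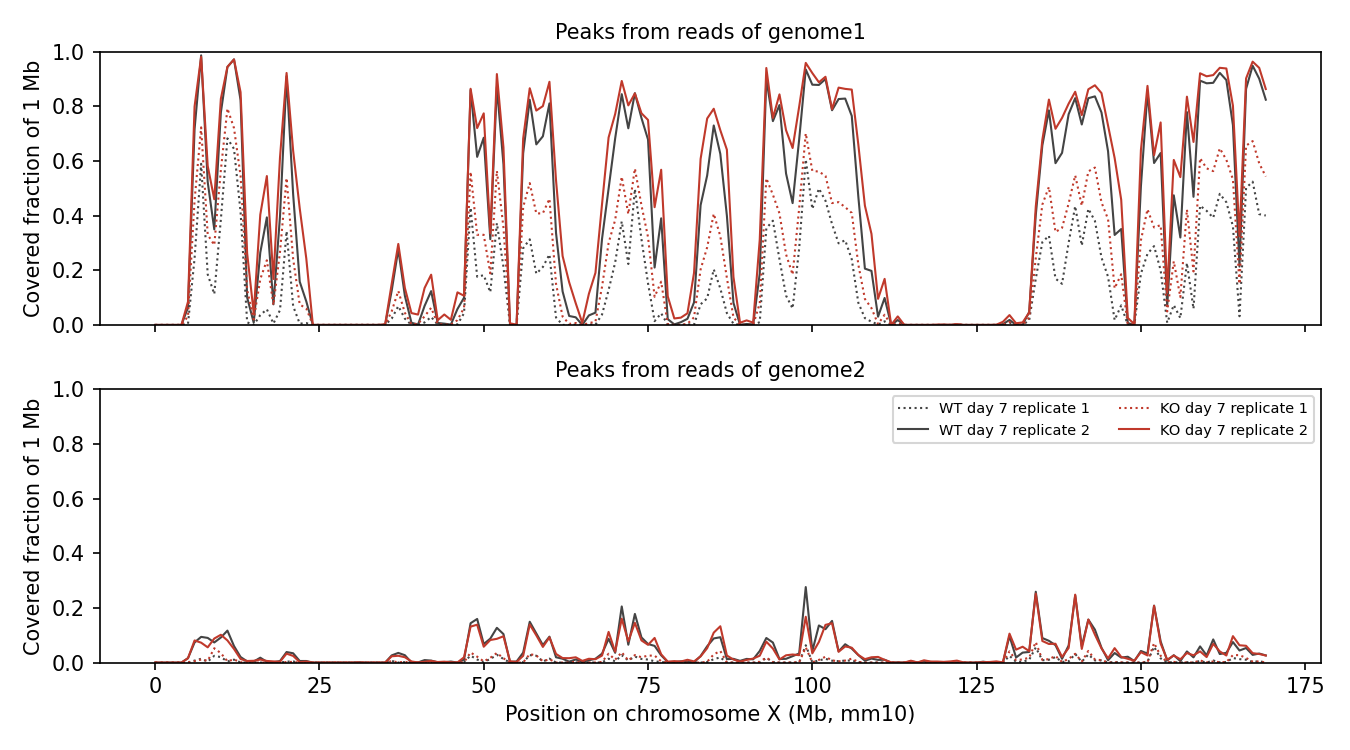
Fraction of each 1 Mb window of chromosome X (horizontal axis, Mb, mm10) covered by genome1 peaks (top) and genome2 peaks (bottom) in the 4 day 7 libraries, WT in grey and KO in red, replicate 1 dotted and replicate 2 solid. Genome1 peaks covered 23.4 to 71.9 Mb of X and genome2 peaks 0.916 to 7.00 Mb.

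The lists called on pooled libraries, 1 per group and so without replicates, were compared by overlap. At day 7, 98.9% of the X bases of the WT list lay in the KO list and 81.5% of those of the KO list in the WT list, whereas on the autosomes it was 48.5% and 91.4%. At day 0 the values were 63.2% and 77.3% on X and 53.4% and 86.8% on the autosomes. The pooled lists covered 74.8 Mb of X in WT and 90.8 Mb in KO at day 7, and 142.8 and 75.8 Mb of the autosomes.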

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

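The test of lists of equal area on the calls made without WT day 0 replicate 1 was set before its result was seen, and the other 5 tests, with the counts and levels of the same genes, were chosen after the results they explain were seen.

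On lists of equal area, camera gave the X-linked genes subject to inactivation as higher in the interaction relative to the other genes (adjusted p = 0.0141). There 0 of the 30 members passed the interaction and 13 rose in each genotype, and an estimated correlation gave 0.999. The lists as deposited gave 0.386, the replicate block 0.249 and the estimated correlation 0.999. Peaks were listed on chromosome Y although the cells are labelled female, numbering 5 and 10 in the WT day 0 libraries, 6 and 9 in KO day 0, 13 and 7 in WT day 7, and 15 and 11 in KO day 7.

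The X to autosome ratio was higher in KO than in WT at day 7. Shorter autosomal lists in KO alone would leave the length of X where it was, but X was longer in KO by 0.38 and 0.19 on the log2 scale within replicate numbers 1 and 2. Autosomal length differed by -0.49 and -0.97 (KO minus WT), the larger part of the ratio in both numbers. The test thus bears only on the case in which X does not move at all, and shorter autosomal lists are not excluded as the main part. Different total lengths of the lists would let the ratio fall to 0 at equal area, and it remained 0.50 and 2.04 higher in KO. The cut itself moved the log2 ratio, however. KO day 7 replicate 1 was the shortest list and stayed whole (0.81). In replicate 2 the cut took WT from -0.99 to -1.51 and KO from 0.17 to 0.53. The equal area test therefore cannot exclude list length. Loss of an X chromosome in part of the WT cells would show in the allelic X ratio at day 0, which has 1 library per genotype (difference -0.13, and 0.227 with both lists of a library at equal length) and leaves this open, as it leaves open a clonal difference in how many cells had inactivated X. It remains a hypothesis that the KO genotype raises H3K27me3 on X relative to the autosomes. The ratio was higher in KO within both numbers at both days (0.39, 0.43, 0.87 and 1.16, with exact paired p = 0.125, the smallest possible, and exact stratified permutation p = 0.167). The ratio does not separate more on X from less on the autosomes. At day 0 the log2 length of X differed by 0.87 and -0.29 (KO minus WT, numbers 1 and 2). Autosomal length differed by 0.48 and -0.72, so in number 2 the higher ratio came from the autosomes.

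Once WT day 0 replicate 1 was left out, 1397 genes passed between KO and WT at day 0, all but 18 lower in KO, for which a candidate explanation is the long list of WT day 0 replicate 2 (256.8 Mb on the autosomes, against 155.4 Mb in KO replicate 2). At equal area 1210 of the 1397 were covered too little to test, and 32 of the 1397 were called the same way. That is under the bound of 10% set beforehand for list length as the cause (50% or more was set if not). The test could hardly end otherwise, since only 187 of the 1397 could be called and the 50% bound was out of reach. Among those 187 the share was 17.1%, a base that the rule had not named. The total called at equal area was seen before the 32 were counted. For the 185 of the 1379 genes lower in KO that were still tested, the median difference went from -0.577 to 0. Over the 1379, the mean covered fraction was 0.666 in WT replicate 2, 0.0735 in the left-out WT replicate 1, and 0.0762 and 0.0880 in KO, and at equal area 0.0385, 0.0459, 0.0290 and 0.0156. Although the bound for list length was met, the length of that list and a genotype difference in weak peaks of replicate 2 cannot be told apart. Most of the genes were no longer tested, and shorter lists drop weak peaks whatever their source.

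The genome1 lists of the day 0 replicate 1 libraries were nearly empty, at 0.184 Mb of autosomes in WT and 1.48 Mb in KO. Relative to replicate 2, the genome1 lists kept 0.00102 (WT) and 0.00818 (KO) of their autosomal length, the genome2 lists 28.8 and 9.57 times that share, and the unassigned lists 709 and 139 times. In themselves the unassigned lists had 0.721 (WT) and 1.13 (KO) times the autosomal length of replicate 2, so that of KO was not shortened. The all-read lists had 0.258 and 0.594 times. A candidate explanation is low yield of the whole library, for which bounds were set of at most 2 times if it was the cause and 10 or more if not, in both genotypes. The 9.57 of KO lies below 10, and the unassigned lists kept 4.84 and 7.00 times at day 7, where no genome1 list was nearly empty, so for them the bound of 2 was wrong (the genome2 lists kept 1.43 and 1.54 times). Low yield and a deficit of genome1 reads alone cannot be told apart, with 1 library per genotype and lists near 0, and no biological explanation was tested.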

How the results depend on the processing

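The X to autosome ratio kept its sign at day 7 and between days in all alternatives run, and KO minus WT at day 7 ranged from 0.55 to 1.48 (log2) over left-out libraries. The depth of reads is unknown and limits all counts. Causes were not tested unless given. The p-values of 2 against 2 could not pass and say nothing of stability.

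The following signs turned. Leaving out a library unpairs the replicate numbers, which differ in level. Without single libraries the ranges were -0.12 to 0.93 for the X to autosome ratio, -1.20 to 1.77 for X length and -1.10 to 0.86 for autosomal length (all KO minus WT, day 0, log2), -1.36 to 0.60 for autosomal length between days in WT, and -0.70 to 1.36 for the allelic X ratio, KO minus WT at day 7. That ratio was -0.0209 by number of peaks, and X length at day 0 was -0.0181 with -log10 q of 2 or more. Among named genes, none of which had passed, the sign turned at equal area for Kcnab1 at day 0 (-0.102) and Lrrc46 and Scrn2 at day 7 (0.0165 each, KO minus WT), for gene bodies for Zkscan2 (-0.0173), and for Xist between days in WT with 5 kb on each side (-0.110) and gene bodies (-0.132). Without single libraries Xist ranged from -0.236 to 0.262 in WT and -0.417 to 0.0839 in KO between days, Otx2 from -0.0671 to 0.845 in KO, and KO minus WT Eomes from -0.0227 to 0.423 at day 0 and Ogt from -0.188 to 0.465 at day 7. Equal area over all libraries left an allelic ratio in KO day 7 replicate 1 alone (-4.27, on 1 X peak of genome1), since in the others the 9 to 351 genome1 peaks left held 0 on X. The level of that ratio at day 7 was 1.25 in WT and 1.63 in KO with equal area among the day 7 libraries, and 1.70 and 1.68 by number of peaks. At day 0, KO minus WT was 0.227 with the genome1 and genome2 lists of a library at equal length.

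For day 7 minus day 0 in WT and KO, gene counts were 941 and 1008 with the replicate block, 974 and 1011 centred, 1186 and 1056 at equal area and 992 and 945 with plain eBayes, and window counts 261 and 434 at equal area and 85 and 121 with 1 Mb windows, of which there are fewer. Without single libraries genes ranged from 0 to 3091 and 0 to 1396, and windows from 481 to 6689 and 684 to 1719. Between genotypes, 1 window passed at day 7 at equal area, and 238 genes at day 0 at equal area without WT day 0 replicate 1. Without single libraries, genes ranged from 0 to 1397 and windows from 0 to 2900 at day 0, and the interaction from 0 to 823 and 0 to 538. Left-out libraries leave a group with 1 sample, assumed to vary like the others.

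Lists passing were 0 and 3 (KO minus WT, days 0 and 7) and 1 (interaction) at equal area, and 0, 0, 2 (WT between days) and 3 (KO) with an estimated correlation. With both, 0 passed in every contrast, where 3 and 5 between genotypes and 7 (WT) and 6 (KO) between days had passed. Without single libraries they ranged from 1 to 4, 0 to 6 and 0 to 5 (interaction).

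Counting a peak as shared when at least 50% is covered gave replicate overlaps of 0.219, 0.334, 0.489 and 0.598 (WT and KO day 0, WT and KO day 7), and pooled overlaps of 58.3% and 74.1% (X) and 46.5% and 85.2% (autosomes) at day 0, and 79.0% (KO in WT, X), 42.0% and 90.5% (autosomes) at day 7. With -log10 q of 2 or more these were 69.1%, 76.0% and 56.9% at day 0, and 49.9% and 94.1% (autosomes) at day 7.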

Other observations

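Imprinted genes, which are expressed from a single parental allele, were compared between genome1 and genome2 lists. In the replicate 2 libraries, 19 (WT day 0), 20 (KO day 0), 18 (WT day 7) and 15 (KO day 7) of 47 imprinted genes had at least 50% of the window covered by genome1 alone, and 0, 0, 1 and 1 by genome2 alone. In the replicate 1 libraries 0, 1, 10 and 9 were covered by genome1 alone and 0 by genome2. Among genes covered by either in the replicate 2 libraries, genome1 alone covered 93.8 to 95.2% of the 16 to 21 imprinted genes and 60.4 to 65.5% of the other autosomal genes (Fisher's exact test, two-sided, p = 0.00153 to 0.00370 for 3 libraries and 0.00444 for KO day 7). Imprinted genes lie in clusters, so the test counts genes that are not independent. Cdkn1c, Grb10 and Phlda2, which are mostly expressed from the maternal allele, and Mest and Plagl1, expressed from the paternal allele, stood on the same side, with 0 from genome2 in all 8 libraries. Gnas, Nnat, Snrpn, Meg3 and Impact had 0 from either genome, and Magel2 and Ndn were covered more by genome2 on average. These genes were chosen after their values were seen.

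A copy of ribosomal DNA sequence on chromosome 17 annotated as Rn18s-rs5 (39846354 to 39848202), singled out after its values were seen because SIRT7 is known to act on ribosomal DNA, held a peak in 4 of 4 day 7 libraries and 0 of 4 day 0 libraries. Its fold enrichment was 14.0 and 4.98 in WT and 11.5 and 3.87 in KO. In each genotype the higher value was that of replicate 1. The input libraries were not analysed, so this peak does not show whether ribosomal DNA gained the mark, which was not tested.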
